A study of Mus musculus with 24 samples.

How the data were processed

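Gene counts were studied in mouse resident dendritic cells (DCs) of the auricular lymph nodes, the nodes that drain the ear. Per the labels, C57BL/6 mice were left naive or received 20 µg of CpG, an oligodeoxynucleotide that activates Toll-like receptor 9 (TLR9), into the skin, and nodes were taken 6 h later. All mice received 3 µg of a fluorescent antibody to CD11c, a DC surface integrin, into the blood 30 minutes before the nodes were taken. Resident DC1 and DC2, the 2 main classes of conventional DC, were sorted as stained (IV-positive) or unstained (IV-negative) by that antibody, 500 cells per sample. RNA was copied with a full-length cDNA kit (SMART-Seq v4), made into Nextera XT libraries and sequenced as paired reads of 59 bases. The labels' molecule and source fields say genomic, while the protocol has cDNA, so RNA was assumed. That kit keeps no strand, so reads from genes that overlap on opposite strands were not told apart.

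Per the submitters' processing notes, reads were aligned with STAR 2.4.2a to build GRCm38 and counted with HTSeq. The annotation, the strand setting and the filter that chose the listed genes are not given in the sources used here. The deposited table gives 1 value per gene and library for 14004 genes in 23 of the 24 libraries in the labels. Naive IV-negative DC1 replicate 1 was not analysed here, which left that group with 2 libraries. The table's name calls the values normalized, but the deposited values are counts: all are whole numbers, their totals ran from 2057588 to 4102346, and median-of-ratios factors between libraries ran from 0.617 to 1.61. A rescaled and rounded table would also leave gaps or doubled integers among low values, and none were found. Every listed gene reaches a count of 10 in at least 1 library.

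The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with a count of at least 1 in at least 3 libraries were kept, which removed 56 genes and left 13948. Libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with a mean for each of 8 groups (treatment, IV stain and cell type) was fitted to all 23 libraries. The CpG comparisons averaged the IV-positive and IV-negative sorts of a cell type. The IV comparisons set IV-positive against IV-negative cells of a cell type, averaged over treatment and within naive or CpG samples. Tests of differences between changes compared DC2 with DC1 after CpG, and the IV difference after CpG with that in naive nodes. The cell type comparison set naive DC2 against naive DC1. P-values are from edgeR's two-sided quasi-likelihood test with the Benjamini-Hochberg correction over all tested genes, at a threshold of 0.05. Log2 differences are given with their standard error (SE), list medians are medians of them, and levels as CPM (counts scaled to library size by TMM) with the standard deviation (SD).

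Before the data were examined, the comparisons, their alternatives, 15 functional gene lists and 14 lists of cell type markers were fixed. The functional lists were interferon-stimulated genes, cytokines, chemokines, TLR9 and NF-kB signalling, DC maturation, MHC class I and class II presentation, adhesion and trafficking receptors, factors acting on vessels, early stress genes, cell cycle, glycolysis, nuclear respiratory chain genes, cholesterol synthesis and mitochondrially encoded transcripts. The marker lists were for cDC1, cDC2, migratory DCs, plasmacytoid DCs, B cells, T cells, NK cells, neutrophils, monocytes, macrophages, endothelium, stromal reticular cells, platelets and erythroid cells. Lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 27 tested lists of a comparison. The platelet and erythroid lists had only 3 and 2 measured genes and were not tested. The migratory DC and DC maturation lists share 5 genes.

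The rule for naming genes was also fixed before the data were examined. For each CpG and cell type comparison it took up to 10 rises and 10 falls with the largest change among genes past the threshold, with a log2 difference of at least 1, a mean of at least 10 CPM in the higher group and the same direction in both IV sorts. For each difference between changes it took 5 in each direction, and for each IV comparison 10 in each direction with no minimum change. Predicted genes and immunoglobulin or T cell receptor segments were skipped. It added up to 4 members of each list with the largest change past the threshold, and always Tlr9, Itgax, Cd4, Cd8a, Xcr1, Sirpa, Tnf, Il12b and Ifnb1. Where all libraries of 1 side had a count of 0, the fold is a lower bound against a floor of 3 counts over that group, and a list median at bounds takes such genes at that value. With 1 to 3 counts, the ratio is given with its 95% counting interval. Such intervals and floors cover counting error only, since reads amplified without molecular identifiers are not independent molecules. Gene positions were taken from GENCODE vM21 on GRCm38. Of 355 named genes, 353 had 1 position, 26 shared over 10% of their exon bases with a gene on the opposite strand and 6 with one on the same strand. Reads of families with near-identical members, such as Iigp1, Gbp, Serpina3, Lyz1 and Lyz2, and Ifi205, can be assigned to the wrong member.

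The alternatives were limma on log2(CPM + 0.1) or log2(CPM + 5), quantile normalization, median-of-ratios size factors, DESeq2 1.42.0, array weights, no filter or a filter of 10 counts in 3 libraries, the replicate number as a block, only the groups compared, leaving out each library in turn, and the estimated correlation for lists. Chosen after seeing the data were limma on log2(CPM + 1), robust edgeR and scaling by library totals only. The procedure was tested on simulated data in which 200 genes were changed by 2-fold or 4-fold. Each comparison with at least 3 libraries per group was repeated on other splits of its libraries, up to 25 in all. In DC1, deviations from group means correlated between IV sorts of 1 replicate number (r 0.152 to 0.286, 5 pairs). The main fit was unpaired. In DC2 (0.0233 to 0.204 over 6 pairs, 3 above 0.1) pairing stayed open. For DC1, all 32 splits that part every pair were also run, a test added after the results were seen. The sequence reads themselves were not used here.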

Results

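Gene counts were obtained from 23 sorted pools of 500 resident DCs: DC1 and DC2, from naive mice or 6 h after CpG, IV-positive or IV-negative. Each of the 8 groups held 3 libraries, except naive IV-negative DC1 with 2. Total counts ran from 2057588 to 4102346 per library, and 12287 to 13244 genes had at least 1 count. The 10 most abundant genes of a library took 6.89% to 12.3% of its counts. Mitochondrial transcripts made up 1.55% ± 0.157 (SD, n = 11) of counts in naive and 1.24% ± 0.222 (SD, n = 12) in CpG libraries. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples.

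The comparison of naive DC2 with naive DC1 gave the identity of the sorted cells at steady state. DC1 carried Xcr1, the XCL1 receptor of cross-presenting DCs, at 1015 ± 161 CPM (mean ± SD, n = 5), against 7.23 ± 4.24 in DC2 (n = 6; log2 difference -7.31 ± 0.30 SE). Cd8a and Cd207, which encodes the lectin langerin, were also lower in DC2, with log2 differences of -4.93 ± 0.20 and -9.51 ± 0.29. DC2 carried Sirpa, an inhibitory receptor that binds CD47, at 486 ± 44.0 CPM against 0.594 ± 0.539 in DC1 (9.76 ± 0.30). Cd209a, a C-type lectin, Cd4 and Mmp12, a macrophage elastase, were higher in DC2 by log2 differences of 11.15 ± 0.29, 4.63 ± 0.41 and 9.83 ± 0.56. Sirpb1a and Clec4a4 had no counts in DC1 and were at least 1793-fold and 392-fold higher in DC2, while Cyp8b1 was at least 367-fold lower. Itgax, which encodes CD11c, was higher in DC2 (364 ± 91.8 against 135 ± 13.7 CPM, 1.42 ± 0.21).

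Among the fixed markers of cDC1, 18 of 18 measured genes were lower and none was higher (the same adjusted over the list alone). The cDC1 list median was -4.11 (camera adjusted p = 2.53e-45, 4.47e-05 with an estimated correlation). Among those of cDC2, 13 of 16 measured genes were higher and 2 lower (13 higher and 3 lower adjusted over the list alone). The cDC2 list median was 5.43 (camera adjusted p = 2.44e-32, 2.92e-05 with an estimated correlation). Several activation groups also differed before CpG. In the TLR9 and NF-kB list, 20 of 28 measured genes were higher and 1 lower (22 higher and 1 lower adjusted over the list alone), with Irak3 (3.66), Tnip3 (3.32) and Relb (1.65) among the higher genes. The NF-kB list median was 0.76 (camera adjusted p = 4.30e-12, 0.0121 with an estimated correlation). For DC maturation, 14 of 25 measured genes were higher and 5 lower (16 higher and 5 lower adjusted over the list alone); Fscn1 and Pdcd1lg2 differed by 6.03 and 4.78. The maturation list median was 0.96 (camera adjusted p = 4.78e-09, 0.0168 with an estimated correlation). Migratory DC markers followed, where 10 of 14 measured genes were higher and 2 lower (the same adjusted over the list alone). The migratory DC list median was 2.64 (camera adjusted p = 0.00143, 0.0258 with an estimated correlation). In MHC class I presentation, 14 of 20 measured genes were lower and none was higher (15 lower adjusted over the list alone), with Psmb9 (-1.97), Tapbpl (-1.66) and Tap2 (-1.58) below DC1. The class I list median was -0.55 (camera adjusted p = 4.22e-12, 0.0314 with an estimated correlation). Factors acting on vessels included Vegfa (5.44), Adm (6.88) and Ptgs2 (6.42), and in that list 9 of 24 measured genes were higher and 2 lower (the same adjusted over the list alone). The vessel factor list median was 1.62 (camera adjusted p = 0.000479, 0.0211 with an estimated correlation). Markers of other cells moved with these groups. For monocytes, 6 of 12 measured genes were higher and none was lower (the same adjusted over the list alone). The monocyte list median was 2.68, or 2.34 at bounds (camera adjusted p = 0.000271, 0.0522 with an estimated correlation). For macrophages, 8 of 12 measured genes were higher and none was lower (the same adjusted over the list alone). The macrophage list median was 3.06, or 2.84 at bounds (camera adjusted p = 3.02e-05, 0.0522 with an estimated correlation). For T cells, 9 of 14 measured genes were higher and none was lower (11 higher adjusted over the list alone). The T cell list median was 0.95 (camera adjusted p = 0.0263, 0.575 with an estimated correlation). Before CpG, 14 of 27 lists passed camera (8 with an estimated correlation), the others by median interferon (0.67), chemokine (0.73, or 0.53 at bounds), receptor (0.52) and respiratory chain (-0.30); the receptor list also passed with an estimated correlation (adjusted p = 0.0299). Between the naive cell types, 4424 genes differed in edgeR's quasi-likelihood test with the Benjamini-Hochberg correction (2382 higher and 2042 lower in DC2), 53.8% higher against 59.5% with library totals only and 46.2% with quantile normalization.

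The CpG comparison in DC1 asked which genes had changed in resident DC1 6 h after a TLR9 ligand was given into the skin. Fscn1, which encodes the actin-bundling protein fascin of mature DCs, rose from 0.432 ± 0.501 CPM in naive DC1 (mean ± SD, n = 5) to 1964 ± 562 after CpG (n = 6; log2 change 11.86 ± 0.30 SE). Ccr7, the chemokine receptor that guides DCs to T cell zones, rose from 175 ± 58.8 to 10209 ± 2033 CPM (5.97 ± 0.17). The cytokine genes Il27 and Il12b rose from 1.95 ± 1.46 to 2514 ± 289 CPM (10.25 ± 0.26) and from 203 ± 112 to 4135 ± 1938 CPM (4.26 ± 0.57). H2-DMb1, part of the chaperone that loads peptides on MHC class II, fell from 1275 ± 93.1 to 25 ± 28.5 CPM (-5.99 ± 0.40). Fscn1 lies on chromosome 5, 142960343 to 142973185 (GRCm38), and Il27 on chromosome 7, 126589010 to 126594941. Il12b lies on chromosome 11, 44400063 to 44414033, Ccr7 on chromosome 11, 99144196 to 99155077 and H2-DMb1 on chromosome 17, 34153072 to 34160230. Il27 shares 10.1% of its exon bases with Apobr on the other strand.

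Among interferon-stimulated genes in DC1, 34 of 34 measured genes rose and none fell (the same adjusted over the list alone). The interferon list median was 4.43 (camera adjusted p = 9.98e-20, 0.151 with an estimated correlation). Gbp5, a GTPase of inflammasome activation, rose from 5.07 ± 5.35 to 519 ± 122 CPM (7.08 ± 0.27), and Ifit1, which binds foreign RNA, by 7.02 ± 0.51. Among cytokines, 18 of 25 measured genes rose and 4 fell (the same adjusted over the list alone), and Tnf rose by 1.14 ± 0.25. The cytokine list median was 3.74 (camera adjusted p = 2.09e-09, 6.04e-05 with an estimated correlation). For chemokines, 14 of 22 measured genes rose and 4 fell (the same adjusted over the list alone). The chemokine list median was 3.13, or 2.41 at bounds (camera adjusted p = 0.0131, 0.364 with an estimated correlation). Ccl5, a chemokine that draws T cells, rose from 14.3 ± 8.37 to 4742 ± 517 CPM (8.35 ± 0.20), and Ccl22 by 6.03 ± 0.40. In the TLR9 and NF-kB list, 22 of 28 measured genes rose and 3 fell (the same adjusted over the list alone), led by Tnip3, an inhibitor of NF-kB (7.28 ± 0.22), and Relb, an NF-kB subunit (4.23 ± 0.11). Across the NF-kB list, the median was 2.04 (camera adjusted p = 5.83e-17, 0.00240 with an estimated correlation). In DC maturation, 22 of 25 measured genes rose and 2 fell (the same adjusted over the list alone), including Cacnb3 (9.09 ± 0.32), the PD-1 ligand Pdcd1lg2 (8.56 ± 0.27) and Socs2 (7.61 ± 0.33). Across the maturation list, the median was 5.11 (camera adjusted p = 6.19e-33, 6.04e-05 with an estimated correlation). Of migratory DC markers, 12 of 14 measured genes rose and 1 fell (the same adjusted over the list alone). Across the migratory DC list, the median was 6.25 (camera adjusted p = 7.40e-10, 0.000190 with an estimated correlation).

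Antigen presentation genes moved both ways in DC1. In MHC class I presentation, 17 of 20 measured genes rose and 2 fell (the same adjusted over the list alone), with Nlrc5, the class I transactivator, up by 2.64 ± 0.16. Across the class I list, the median was 1.49 (camera adjusted p = 7.37e-09, 0.122 with an estimated correlation). In MHC class II presentation, 2 of 14 measured genes rose and 11 fell (the same adjusted over the list alone). The class II list median was -2.48 (camera adjusted p = 0.000932, 0.410 with an estimated correlation). Ciita, the class II transactivator, and Marchf1, a ligase that removes class II from the surface, fell (-5.32 ± 0.47 and -5.29 ± 0.30), while the protease gene Lgmn rose (5.36 ± 0.20). Markers of cDC1 identity fell: 2 of 18 measured genes rose and 14 fell (the same adjusted over the list alone). Across the cDC1 list, the median was -3.93 (camera adjusted p = 9.56e-05, 0.122 with an estimated correlation). Xcr1 fell from 1015 ± 161 to 64.4 ± 41.2 CPM (-4.06 ± 0.25), as did Tlr3, a sensor of double-stranded RNA (-6.14 ± 0.30), Cd207 (-7.78 ± 0.28) and Itgax (-2.83 ± 0.24). Log2 changes of Cd8a (0.05 ± 0.17, adjusted p = 0.822) and Tlr9 (0.78 ± 0.45, adjusted p = 0.142) did not pass edgeR's quasi-likelihood test with the Benjamini-Hochberg correction. In the early stress list, 6 of 24 measured genes rose and 13 fell (the same adjusted over the list alone), among them Egr1 and Egr2 (-3.36 ± 0.21 and -5.05 ± 0.48). The early stress list median was -0.68 (camera adjusted p = 0.00687, 0.496 with an estimated correlation).

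Other large rises in DC1 were Pdzk1ip1 (11.77 ± 0.37) and the stress protein gene Nupr1 (11.21 ± 0.27). Wfdc21, Elobl and Flrt3 had no counts in naive DC1 and rose at least 381-fold, 374-fold and 336-fold. Slfn4 had 1 to 3 counts in naive DC1 and rose by a ratio of 2709 (95% counting interval 749 to 22374). Cyp8b1 fell at least 175-fold, and Slc9a9 by a ratio of 296 (95% counting interval 101 to 1439). Neutrophil markers moved with the rises: 6 of 10 measured genes rose and none fell (the same adjusted over the list alone), and Lcn2, S100a9 and S100a8, absent from naive DC1, were at least 255-fold, 327-fold and 259-fold higher. The neutrophil list median was 6.36, or 4.79 at bounds (camera adjusted p = 0.409, 0.885 with an estimated correlation). Of 13948 genes, 8270 changed in DC1 in edgeR's quasi-likelihood test with the Benjamini-Hochberg correction (3975 rose, 4295 fell). Within the IV-negative and IV-positive sorts alone the counts were 6288 and 6886. TMM factors were 1.16 to 1.26 in naive and 0.774 to 0.936 in CpG libraries, so changes are relative to that scaling. With library totals only, chosen after seeing the data, the CpG effect in DC1 gave 9163 genes, 28.0% of them higher against 48.1%, with the median of all genes at -0.64 against -0.07.

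**Figure D1:**
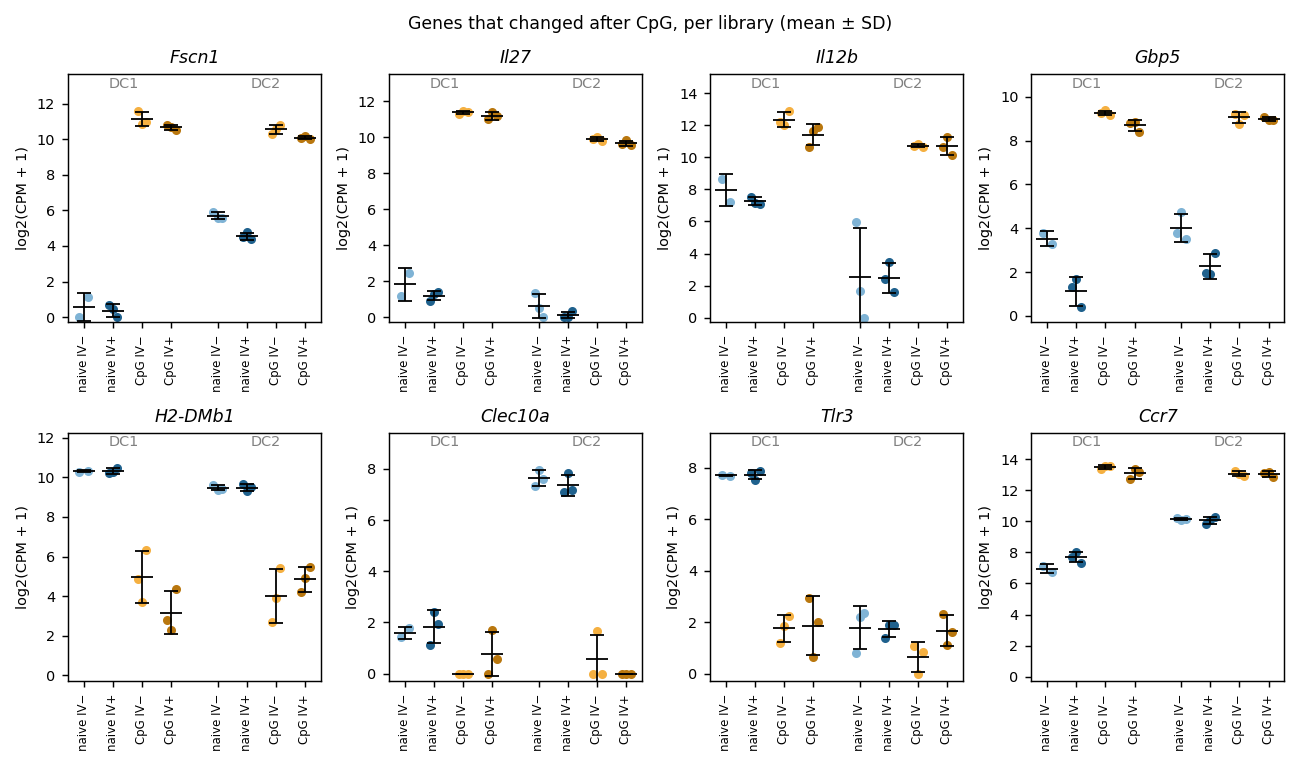
Levels of 8 genes named for the CpG comparisons, as log2(CPM + 1), in the 8 groups; points are libraries, and the line and bars are the mean ± SD. Fscn1, Il27, Il12b, Gbp5 and Ccr7 were higher after CpG in DC1 and DC2, while H2-DMb1 was lower in both, Clec10a in DC2 and Tlr3 in DC1.

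The CpG comparison in DC2 asked the same question of the other resident class. Il27 rose from 0.368 ± 0.590 CPM in naive DC2 (mean ± SD, n = 6) to 883 ± 103 after CpG (n = 6; log2 change 11.58 ± 0.26 SE), and Il12b from 13.2 ± 23.6 to 1729.5 ± 444 CPM (7.32 ± 0.62). Cxcl9 and Cxcl10, ligands of CXCR3, a receptor of activated T cells, rose from 58.3 ± 25 to 2486 ± 509.5 and from 175 ± 125 to 4759 ± 561 CPM (5.42 ± 0.26 and 4.88 ± 0.29). The lectin gene Clec10a fell from 184 ± 45.4 to 0.364 ± 0.893 CPM (-9.96 ± 0.47). Csf1r, the receptor of a growth factor for myeloid cells, fell from 286 ± 63.7 to 0.870 ± 0.792 CPM (-8.85 ± 0.32). Clec10a lies on chromosome 11, 70156197 to 70170834 (GRCm38) and Csf1r on chromosome 18, 61100598 to 61132149, with 15.1% of Csf1r's exon bases shared with Hmgxb3 on the other strand.

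Among interferon-stimulated genes in DC2, 34 of 34 measured genes rose and none fell (the same adjusted over the list alone), with Gbp5 up by 6.01 ± 0.21 and Oasl1 by 5.94 ± 0.37. Across the interferon list, the median was 4.14 (camera adjusted p = 2.73e-27, 0.0477 with an estimated correlation). Cytokine genes moved likewise: 19 of 25 measured genes rose and 3 fell (19 and 4 adjusted over the list alone). Across the cytokine list, the median was 2.7 (camera adjusted p = 3.04e-12, 2.09e-05 with an estimated correlation). Tnf rose from 93.9 ± 27.2 to 294 ± 101 CPM (1.64 ± 0.24). Ifnb1, encoding interferon beta, had no counts in naive DC2, reached 4.41 ± 3.26 CPM and rose at least 35.1-fold. For chemokines, 13 of 22 measured genes rose and 2 fell (the same adjusted over the list alone). Across the chemokine list, the median was 1.48 (camera adjusted p = 0.000402, 0.0804 with an estimated correlation). In the TLR9 and NF-kB list, 18 of 28 measured genes rose and 5 fell (the same adjusted over the list alone), with the feedback genes Socs1 and Socs3 up by 3.87 ± 0.17 and 2.80 ± 0.17, and Tlr9 by 1.70 ± 0.38. The NF-kB list median was 0.98 (camera adjusted p = 3.59e-07, 0.0477 with an estimated correlation). In DC maturation, 21 of 25 measured genes rose and none fell (the same adjusted over the list alone), led by Ido1, which degrades tryptophan (7.86 ± 0.68), and Tnfrsf9 (6.74 ± 0.30). The maturation list median was 2.86 (camera adjusted p = 1.24e-32, 4.03e-05 with an estimated correlation). Of migratory DC markers, 11 of 14 measured genes rose and 1 fell (11 and 2 adjusted over the list alone). The migratory DC list median was 2.73 (camera adjusted p = 1.81e-08, 0.000138 with an estimated correlation).

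In MHC class I presentation in DC2, 17 of 20 measured genes rose and 1 fell (the same adjusted over the list alone), with Tapbpl and Nlrc5 up by 3.16 ± 0.18 and 3.02 ± 0.14. The class I list median was 2.12 (camera adjusted p = 2.04e-20, 0.00684 with an estimated correlation). In MHC class II presentation, 1 of 14 measured genes rose and 11 fell (the same adjusted over the list alone); H2-DMb1 (-4.83 ± 0.36) and H2-Oa (-4.19 ± 0.28) fell. Across the class II list, the median was -2.62 (camera adjusted p = 6.05e-07, 0.102 with an estimated correlation). Markers of cDC2 identity fell: 13 of 16 measured genes fell and none rose (the same adjusted over the list alone). Across the cDC2 list, the median was -2.22 (camera adjusted p = 3.86e-10, 0.000577 with an estimated correlation). Cd4 and Sirpa changed by -4.60 ± 0.36 and -1.84 ± 0.14, and Itgax by -2.74 ± 0.21. Cd8a rose from 40.7 ± 31.2 to 137 ± 38.0 CPM (2.11 ± 0.18) and Ly75, the endocytic receptor DEC-205 of cDC1, from 10.4 ± 3.95 to 584 ± 52.8 CPM (5.87 ± 0.16), whereas among all cDC1 markers 5 of 18 measured genes rose and 11 fell (5 and 12 adjusted over the list alone). The cDC1 list median was -2.43 (camera adjusted p = 0.930, 0.966 with an estimated correlation). The cDC1 median was below 0 while camera's direction was up. Of cell cycle genes, 2 of 24 measured genes rose and 19 fell (the same adjusted over the list alone), including E2f1 (-2.35 ± 0.31). The cell cycle list median was -0.76 (camera adjusted p = 0.0234, 0.767 with an estimated correlation). In the early stress list, 8 of 24 measured genes rose and 14 fell (9 and 14 adjusted over the list alone). Across the early stress list, the median was -0.73 (camera adjusted p = 0.0310, 0.696 with an estimated correlation).

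Slfn4, Lcn2, Hamp and Ddn had no counts in naive DC2 and rose at least 1978-fold, 1209.6-fold, 737-fold and 602-fold. Cd300lg, Hr and the scavenger receptor gene Cd163 had none after CpG and fell at least 233-fold, 166-fold and 78.8-fold. Of macrophage markers, 1 of 12 measured genes rose and 4 fell (the same adjusted over the list alone), and the list did not pass camera. Across the macrophage list, the median was -1.30 (camera adjusted p = 0.200, 0.767 with an estimated correlation). In edgeR's quasi-likelihood test with the Benjamini-Hochberg correction, 7836 genes changed in DC2 (3764 rose, 4072 fell), with 6082 and 5976 within the IV-negative and IV-positive sorts. With library totals only, the CpG effect in DC2 gave 9071 genes, 26.4% of them higher against 48.0%, and a median of all genes of -0.56 against -0.10.

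The difference between the CpG changes of DC2 and DC1 was tested directly. Irf8, a transcription factor needed for cDC1, fell in DC1 from 1681 ± 234 to 679 ± 129 CPM and rose in DC2 from 80.1 ± 27.4 to 1056 ± 112 (difference of log2 changes 5.10 ± 0.20 SE, n = 5 and 6 libraries in naive and CpG DC1 and 6 and 6 in DC2). Sirpa went the other way, from 0.594 ± 0.539 to 9.23 ± 3.15 CPM in DC1 and from 486 ± 44.0 to 137 ± 32.1 in DC2 (-5.89 ± 0.43). Fscn1, higher in naive DC2 than naive DC1, rose less in DC2 (-6.62 ± 0.36), as did Ccr7 (-3.01 ± 0.18). Cxcl9 rose more in DC2 (4.69 ± 0.33). Irf8 lies on chromosome 8, 120736358 to 120756694 (GRCm38).

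Of the DC maturation list, 4 of 25 measured genes were higher and 15 lower (the same adjusted over the list alone) in DC2 than in DC1. Across the maturation list, the median was -1.68 (camera adjusted p = 1.56e-13, 0.00380 with an estimated correlation). For the TLR9 and NF-kB list, 1 of 28 measured genes was higher and 18 lower (2 higher and 18 lower adjusted over the list alone), with Irak3 and Tnip3 at -4.86 and -3.74. Across the NF-kB list, the median was -0.87 (camera adjusted p = 1.61e-16, 0.00380 with an estimated correlation). Migratory DC markers gave a like picture, where 11 of 14 measured genes were lower and none was higher (the same adjusted over the list alone). Across the migratory DC list, the median was -3.11 (camera adjusted p = 4.13e-15, 4.12e-05 with an estimated correlation). For cDC1 markers, 8 of 18 measured genes were higher and none was lower (the same adjusted over the list alone), with Irf8 and Tlr3 (5.06) in front. Across the cDC1 list, the median was 1.67 (camera adjusted p = 8.81e-09, 0.0381 with an estimated correlation). For cDC2 markers, 1 of 16 measured genes was higher and 5 lower (1 higher and 6 lower adjusted over the list alone). The cDC2 list median was -2.55 (camera adjusted p = 0.00858, 0.269 with an estimated correlation). In MHC class I presentation, 11 of 20 measured genes were higher and 2 lower (12 higher and 3 lower adjusted over the list alone). Across the class I list, the median was 0.49 (camera adjusted p = 0.000108, 0.327 with an estimated correlation). Of interferon-stimulated genes, 4 of 34 measured genes were higher and 11 lower (4 higher and 12 lower adjusted over the list alone), and Oas2 and Ifit1 stood at -2.61 and -2.50. The interferon list median was -0.39 (camera adjusted p = 0.198, 0.990 with an estimated correlation). Vegfa, the vascular endothelial growth factor, fell from 78.7 ± 18.6 to 5.19 ± 0.777 CPM in DC2 (difference -4.01 ± 0.71).

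The largest differences were Alpl (7.54 ± 1.47), Gpr31b (7.29 ± 1.32) and Havcr1 (6.87 ± 1.66) toward DC2, and Ackr1 (-10.55 ± 1.23), Kcne3 (-10.04 ± 0.61) and Flrt3 (-8.79 ± 0.75) toward DC1; Ackr1 shares 25.7% of its exon bases with Cadm3 on the same strand. The CpG change of 3531 genes differed in edgeR's quasi-likelihood test with the Benjamini-Hochberg correction (1756 higher and 1775 lower in DC2). With library totals only, the CpG effect DC2 minus DC1 had 59.2% of its genes higher against 49.7%, with the median of all genes at 0.11. Rises of at least 2-fold past the threshold were shared by 1657 genes (436.3 by chance) and falls by 1747 (606.0 by chance), while 73 genes changed in opposite directions. Across all tested genes the log2 changes in DC1 and DC2 had a Pearson r of 0.712 and a Spearman rho of 0.710, where genes are not independent replicates.

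**Figure D2:**
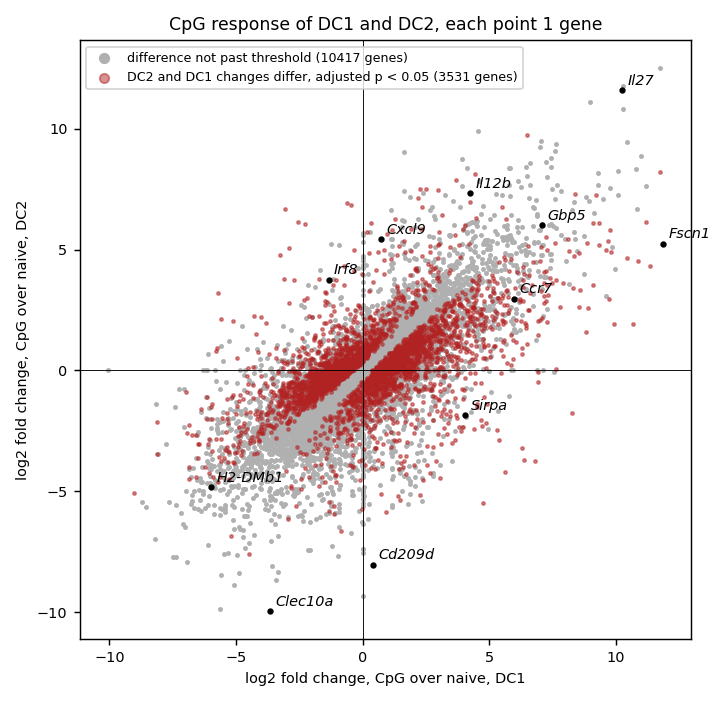
Log2 change after CpG in DC1 (x axis) and DC2 (y axis) for each tested gene; red points are the 3531 genes whose changes differed between DC1 and DC2, and gray points the other tested genes. Irf8 lies off the diagonal on the DC2 side, and Sirpa and Fscn1 on the DC1 side.

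The IV comparison in DC1 asked how resident DC1 reached by an antibody in the blood differ from those it did not reach. Cell division genes were higher in IV-positive DC1. Top2a, the topoisomerase of dividing cells, averaged 166 ± 22.6 CPM in 6 IV-positive and 65.7 ± 21.4 in 5 IV-negative libraries (mean ± SD; log2 difference 1.33 ± 0.19 SE). Ube2c, which drives mitotic exit, averaged 206 ± 47.8 against 65.0 ± 40.6 CPM (1.65 ± 0.30), and the mitotic kinase gene Plk1 differed by 1.84 ± 0.34. The interferon-inducible GTPase gene Iigp1 was lower on average over naive and CpG samples (-2.14 ± 0.24), through its difference in naive DC1 (given with that comparison). Also lower was Egr1, an immediate early transcription factor (120.4 ± 25.4 against 322 ± 102 CPM in naive and 10.1 ± 5.41 against 36.3 ± 5.29 in CpG samples; -1.63 ± 0.21 over both). Within each treatment, every IV-positive library lay above every IV-negative one for Top2a, Ube2c and Plk1, and below for Egr1.

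In the cell cycle list in IV-positive DC1, 10 of 24 measured genes were higher and none was lower (20 higher adjusted over the list alone). Across the cell cycle list, the median was 0.81 (camera adjusted p = 1.63e-35, 0.00852 with an estimated correlation and 0.0785 when the replicate number was also a block). Markers of T cells moved with it: 0 of 14 measured genes passed (9 higher adjusted over the list alone). Across the T cell list, the median was 0.88 (camera adjusted p = 3.15e-07, 0.203 with an estimated correlation). For macrophages, 0 of 12 measured genes passed (the same adjusted over the list alone). The macrophage list median was 1.28, or 1.03 at bounds (camera adjusted p = 0.0160, 0.360 with an estimated correlation). A higher median, that of neutrophil (1.58; adjusted p = 0.882, 0.960 with an estimated correlation) markers, did not pass camera. Camera passed 12 of 27 lists (3 with an estimated correlation, lost with the block), the others by median maturation (-0.18), class I (-0.13), class II (-0.16), respiratory chain (0.15), cholesterol synthesis (-0.55) and cDC1 (-0.33). Among interferon-stimulated genes, 2 of 34 measured genes were lower and none was higher (8 lower adjusted over the list alone), with Gbp5 at -1.77 ± 0.29. Across the interferon list, the median was -0.50 (camera adjusted p = 1.65e-10, 0.360 with an estimated correlation). For the early stress list, 2 of 24 measured genes were lower and none was higher (7 lower adjusted over the list alone). The early stress list median was -0.34 (camera adjusted p = 1.37e-11, 0.0459 with an estimated correlation and 0.0788 when the replicate number was also a block). For the TLR9 and NF-kB list, 1 of 28 measured genes was lower and none was higher (10 lower adjusted over the list alone). The NF-kB list median was -0.22 (camera adjusted p = 4.23e-06, 0.112 with an estimated correlation). Serpina3g, a serine protease inhibitor of activated leukocytes, and Tgtp1, a GTPase, were lower, at -1.21 ± 0.19 and -1.13 ± 0.19. Itgax did not pass edgeR's quasi-likelihood test with the Benjamini-Hochberg correction (-0.35 ± 0.25, adjusted p = 0.639). Top2a lies on chromosome 11, 98992943 to 99024189 (GRCm38), and Ube2c on chromosome 2, 164769898 to 164778822. Iigp1 lies on chromosome 18, 60376027 to 60392634 and Egr1 on chromosome 18, 34859823 to 34864984. Ube2c shares 22.8% of its exon bases with Tnnc2 on the other strand. In that test 110 genes differed (53 higher, 57 lower), 161 with the replicate number as a block, and 57 higher and 38 lower with library totals only. The IV label effect in DC1 gave 13 without naive IV-negative DC1 replicate 2, 61 without naive IV-negative DC1 replicate 3, 73 without naive IV-positive DC1 replicate 1, 51 without naive IV-positive DC1 replicate 3, 66 without CpG IV-negative DC1 replicate 1, 33 without CpG IV-negative DC1 replicate 3 and 64 without CpG IV-positive DC1 replicate 3. Top2a, Iigp1, Egr1, Serpina3g and Tgtp1 passed without any 1 library. DESeq2 gave 334 genes and array weights 233.

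Within naive DC1, the IV-positive cells (n = 3) had lower levels of several interferon-inducible genes than the IV-negative cells (n = 2). Iigp1 averaged 3.71 ± 2.91 against 64.4 ± 2.38 CPM (log2 difference -4.05 ± 0.40 SE), Serpina3g 290.0 ± 58.0 against 956 ± 155 (-1.72 ± 0.27), and Irf1, an interferon-induced transcription factor, 109.5 ± 14.9 against 278 ± 22.7 (-1.34 ± 0.18). Gbp5 and Cxcl11, a CXCR3 ligand, were lower, at -2.97 ± 0.53 and -2.49 ± 0.51, not passing with the replicate number as a block (adjusted p = 0.0887); Cxcl11 shares 41.7% of its exon bases with Gm2673 on the other strand. Stmn1, a microtubule regulator of dividing cells, was higher (1.25 ± 0.23). In the interferon-stimulated list, 1 of 34 measured genes was lower and none was higher (8 lower adjusted over the list alone). The interferon list median was -0.60 (camera adjusted p = 1.23e-10, 0.288 with an estimated correlation). Of cell cycle genes, 0 of 24 measured genes passed (18 higher adjusted over the list alone), and T cell markers moved with it (median log2 difference 1.10, camera adjusted p = 2.21e-09, adjusted p = 0.168 with an estimated correlation). The cell cycle list median was 0.98 (camera adjusted p = 1.11e-25, 0.0323 with an estimated correlation and 0.119 when the replicate number was also a block). Within naive DC1, 14 of 27 lists passed camera (1 with an estimated correlation), the others by median cytokine (-0.52), chemokine (-0.30), NF-kB (-0.32), maturation (-0.11), class I (-0.24), class II (-0.20), early stress (-0.21), respiratory chain (0.08), cholesterol synthesis (-0.38), B cell (0.65) and macrophage (1.05); the B cell list did not pass with the replicate number as a block (adjusted p = 0.124). In edgeR's quasi-likelihood test with the Benjamini-Hochberg correction, 22 genes differed (5 higher, 17 lower), but 52 higher and 31 lower with only the groups compared and 58 higher and 53 lower with array weights. The IV label effect in naive DC1 gave 4 without naive IV-negative DC1 replicate 2, 11 without naive IV-negative DC1 replicate 3, 10 without naive IV-positive DC1 replicate 2 and 4 without naive IV-positive DC1 replicate 3, and 42 with the replicate number as a block. Iigp1 and Irf1 passed without any 1 library, and the other settings gave 20 to 111 genes.

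After CpG, IV-positive DC1 (n = 3) again had higher cell division genes than IV-negative DC1 (n = 3). Ube2c averaged 211 ± 49.1 against 44.2 ± 36.3 CPM (log2 difference 2.25 ± 0.41 SE), with 1 IV-negative library, replicate 3, at 4.19. Plk1 and Top2a were higher by 2.31 ± 0.48 and 1.36 ± 0.25. Egr1, the prion protein gene Prnp and the junctional adhesion gene F11r were lower, at -1.84 ± 0.34, -1.32 ± 0.22 and -1.28 ± 0.24. In the cell cycle list, 3 of 24 measured genes were higher and none was lower (14 higher adjusted over the list alone). Across the cell cycle list, the median was 0.81 (camera adjusted p = 2.62e-19, 0.0586 with an estimated correlation). In the early stress list, 2 of 24 measured genes were lower and none was higher (12 lower adjusted over the list alone). Across the early stress list, the median was -0.49 (camera adjusted p = 7.70e-12, 0.0586 with an estimated correlation). Neutrophil markers moved with these groups: 0 of 10 measured genes passed (5 higher adjusted over the list alone). Across the neutrophil list, the median was 3.24, or 3.00 at bounds (camera adjusted p = 0.000797, 0.294 with an estimated correlation). Markers of cDC1 were lower (median log2 difference -0.49, camera adjusted p = 0.0238, adjusted p = 0.504 with an estimated correlation), but camera's direction turned without CpG IV-negative DC1 replicate 3. Within CpG DC1, 10 of 27 lists passed camera (0 with an estimated correlation), the others by median interferon (-0.31), maturation (-0.19), respiratory chain (0.21), cholesterol synthesis (-0.51), T cell (0.53) and macrophage (1.17, or 0.63 at bounds). S100a8 stood at 209, 69.0 and 8.14 CPM in the 3 IV-positive libraries and 10.6 ± 4.16 in IV-negative ones. In edgeR's quasi-likelihood test with the Benjamini-Hochberg correction, 19 genes differed (7 higher, 12 lower), and 38 with the replicate number as a block. The IV label effect in CpG DC1 gave 4 without CpG IV-negative DC1 replicate 1, 1 without CpG IV-negative DC1 replicate 3, 0 without CpG IV-positive DC1 replicate 1, 10 without CpG IV-positive DC1 replicate 2 and 5 without CpG IV-positive DC1 replicate 3. No named gene passed in all 6 of these fits, and the other settings gave 12 to 100 genes. The neutrophil list lost its call without CpG IV-positive DC1 replicate 1.

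**Figure D3:**
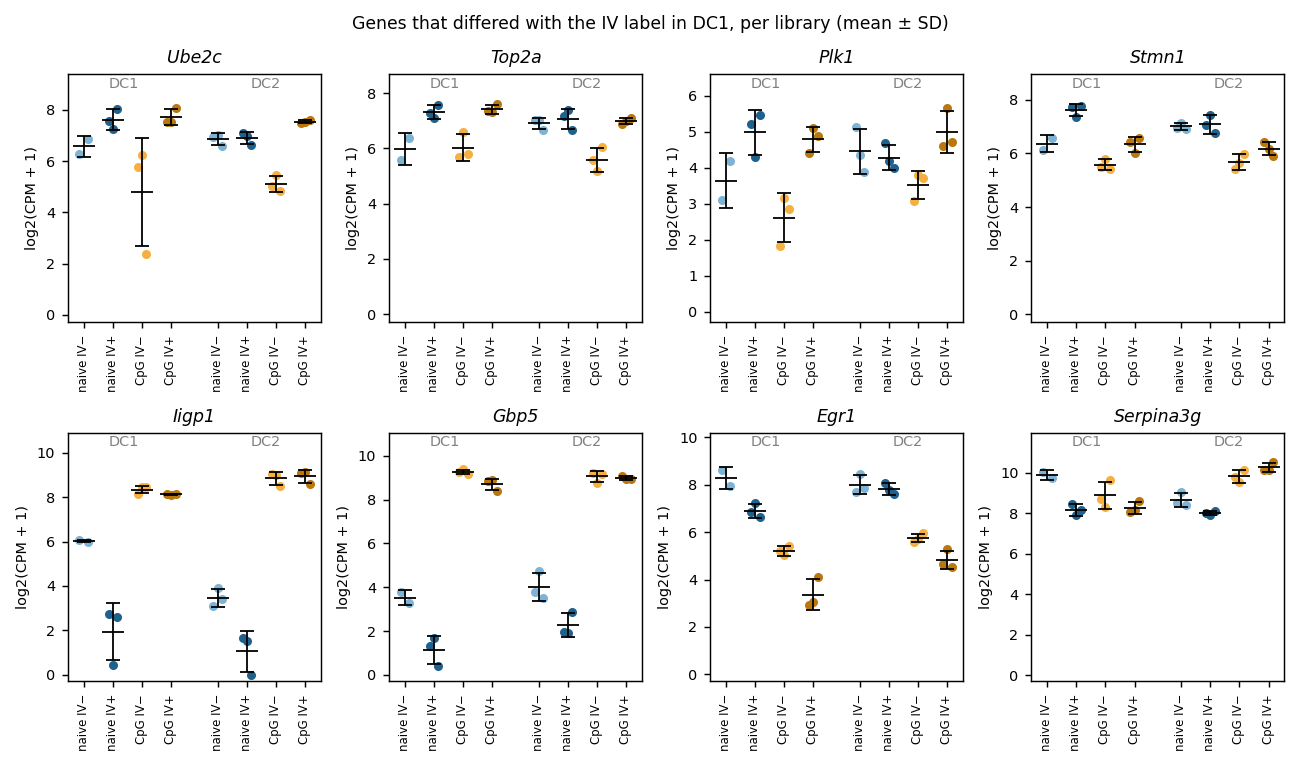
Levels of 8 genes named for the IV comparisons in DC1, as log2(CPM + 1), in the 8 groups; points are libraries, and the line and bars are the mean ± SD. Ube2c, Top2a and Plk1 lay higher in every IV-positive than in every IV-negative DC1 library of the same treatment, and Iigp1 was lower in naive IV-positive DC1.

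The IV comparison in DC2 asked the same of the other class. Apol7c, an apolipoprotein L gene of DCs, was lower in IV-positive DC2, at 181 ± 90.7 against 493 ± 183 CPM in CpG samples (mean ± SD, n = 3 each; log2 difference over naive and CpG samples -2.58 ± 0.32 SE). Averaged over naive and CpG samples, Fscn1 and Cacnb3, genes of mature DCs, were lower in IV-positive DC2 (-0.83 ± 0.14 and -1.40 ± 0.21), as was Cd8a (-1.28 ± 0.18). The Cacnb3 difference lay in naive DC2 (-2.74 ± 0.34), with 841 ± 79.1 against 882 ± 72.5 CPM after CpG. Cd8a did not pass after CpG (-0.38 ± 0.24, adjusted p = 0.659). Mmp12 and the lysozyme gene Lyz1 were higher by 1.71 ± 0.28 and 1.70 ± 0.32, and Lpl, which splits lipoprotein fats, by 3.19 ± 0.61. Aldh1a2, which makes retinoic acid, and Cadm1, an adhesion molecule, were higher by 1.51 ± 0.31 and 1.97 ± 0.38.

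Of migratory DC markers in IV-positive DC2, 1 of 14 measured genes was higher and 2 lower (1 higher and 8 lower adjusted over the list alone). The migratory DC list median was -0.78 (camera adjusted p = 1.56e-05, 0.00626 with an estimated correlation). In DC maturation, 1 of 25 measured genes was higher and 4 lower (2 higher and 6 lower adjusted over the list alone). The maturation list median was -0.12 (camera adjusted p = 7.91e-05, 0.215 with an estimated correlation). Of 24 measured cell cycle genes, 3 were higher and none was lower (13 higher adjusted over the list alone), with Ube2c at 1.24 ± 0.27. The list median was 0.42 (camera adjusted p = 7.91e-05, 0.467 with an estimated correlation), with -0.18 in naive and 0.99 in CpG DC2. Markers of other cells moved with these groups. For B cells, 0 of 14 measured genes passed (5 higher adjusted over the list alone). The B cell list median was 0.86 (camera adjusted p = 7.91e-05, 0.286 with an estimated correlation). For T cells, 0 of 14 measured genes passed (the same adjusted over the list alone). The T cell list median was -0.55 (camera adjusted p = 0.000659, 0.474 with an estimated correlation). In sum, 13 of 27 lists passed camera (1 with an estimated correlation), the others by median interferon (-0.15), class II (0.22), early stress (-0.10), respiratory chain (0.06), cDC1 (-0.17), cDC2 (0.28), NK cell (-0.30) and monocyte (0.25); camera's direction for interferon turned without naive IV-positive DC2 replicate 2. Itgax did not pass edgeR's quasi-likelihood test with the Benjamini-Hochberg correction (0.46 ± 0.20, adjusted p = 0.404). Apol7c lies on chromosome 15, 77524852 to 77533316 (GRCm38), Cacnb3 on chromosome 15, 98630840 to 98644529, Cd8a on chromosome 6, 71373427 to 71379173 and Mmp12 on chromosome 9, 7344381 to 7369499. In that test 68 genes differed (34 higher, 34 lower), and DESeq2 gave 156, only the groups compared 38 and limma on log2(CPM + 0.1) 6 higher and 16 lower. The IV label effect in DC2 gave 43 without naive IV-negative DC2 replicate 1, 16 without naive IV-negative DC2 replicate 2, 41 without naive IV-positive DC2 replicate 1, 45 without CpG IV-positive DC2 replicate 1, 35 without CpG IV-positive DC2 replicate 2 and 31 without CpG IV-positive DC2 replicate 3. Apol7c, Fscn1, Cacnb3, Cd8a, Mmp12 and Lyz1 passed without any 1 library.

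Within naive DC2, IV-positive cells (n = 3) had lower levels of a small set of genes than IV-negative cells (n = 3). Apol7c averaged 10.1 ± 5.07 against 131 ± 85.4 CPM (log2 difference -3.72 ± 0.50 SE). Ifi205, an interferon-inducible DNA sensor gene, averaged 3.07 ± 2.19 against 34.9 ± 14.7 (-3.53 ± 0.37), and Cacnb3 4.84 ± 3.70 against 32.2 ± 12.3 (-2.74 ± 0.34). Cd8a averaged 14.4 ± 7.72 against 67.0 ± 17.2 (-2.19 ± 0.27). Every IV-positive library lay below every IV-negative one for these 4 genes. Fscn1 and Relb were lower, at -1.17 ± 0.22 and -0.66 ± 0.13, and the phospholipid transfer gene Pltp was higher (1.5 ± 0.31). Ifi205 lies on chromosome 1, 174011998 to 174031810 (GRCm38).

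Of migratory DC markers in naive IV-positive DC2, 2 of 14 measured genes were lower and none was higher (2 higher and 4 lower adjusted over the list alone). Across the migratory DC list, the median was -0.67 (camera adjusted p = 3.43e-05, 0.0165 with an estimated correlation). In DC maturation, 3 of 25 measured genes were lower and none was higher (1 higher and 6 lower adjusted over the list alone). Across the maturation list, the median was -0.29 (camera adjusted p = 8.54e-07, 0.0512 with an estimated correlation). Of cDC1 markers, 1 of 18 measured genes was lower and none was higher (2 higher and 6 lower adjusted over the list alone). The cDC1 list median was -0.58 (camera adjusted p = 8.54e-07, 0.0972 with an estimated correlation). Other cells' markers moved with these groups. For B cells, 0 of 14 measured genes passed (10 higher adjusted over the list alone), with Cd79a, a chain of the B cell receptor, at 89.3 ± 42.8 against 23.4 ± 14.5 CPM. Across the B cell list, the median was 1.46 (camera adjusted p = 6.85e-09, 0.0512 with an estimated correlation). For NK cells, 0 of 11 measured genes passed (3 lower adjusted over the list alone). The NK cell list median was -1.38 (camera adjusted p = 3.11e-06, 0.0972 with an estimated correlation). Altogether, 8 of 27 lists passed camera (1 with an estimated correlation), the others by median interferon (-0.29), mitochondrially encoded (0.16) and macrophage (-1.19); camera's direction for interferon turned without naive IV-positive DC2 replicate 2. In edgeR's quasi-likelihood test with the Benjamini-Hochberg correction, 24 genes differed (2 higher, 22 lower), and DESeq2 gave 83 and array weights 15 higher and 15 lower. Mitochondrial transcripts took 1.56% ± 0.0985 of counts in IV-positive and 1.35% ± 0.0375 in IV-negative libraries (SD, n = 3), and ribosomal protein genes 2.96% ± 0.134 and 2.56% ± 0.0177, both without overlap. The IV label effect in naive DC2 gave 8 without naive IV-negative DC2 replicate 2 and 5 with only the groups compared. Apol7c, Ifi205, Cacnb3 and Cd8a passed without any 1 library.

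After CpG, IV-positive DC2 (n = 3) had more genes higher than lower relative to IV-negative DC2 (n = 3). Hk3, a hexokinase of myeloid cells, averaged 24 ± 7.95 against 2.16 ± 0.693 CPM (log2 difference 3.48 ± 0.58 SE). Ube2c averaged 184 ± 7.90 against 34.1 ± 7.68 (2.42 ± 0.41), Mmp12 181 ± 50.6 against 36.0 ± 14.2 (2.34 ± 0.42) and Aldh1a2 188 ± 65.3 against 39.3 ± 6.39 (2.26 ± 0.38). Lyz1 and Lyz2, the lysozyme genes, were higher by 2.36 ± 0.47 and 1.92 ± 0.38. Arpin, an inhibitor of the Arp2/3 complex, was lower (-1.79 ± 0.19). Every IV-positive library lay above every IV-negative one for Hk3, Ube2c, Mmp12, Aldh1a2 and Lyz1, and below for Arpin. Hk3 lies on chromosome 13, 55005985 to 55021385 (GRCm38).

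In the cell cycle list in IV-positive DC2 after CpG, 8 of 24 measured genes were higher and none was lower (14 higher and 1 lower adjusted over the list alone). Across the cell cycle list, the median was 0.99 (camera adjusted p = 5.11e-14, 0.286 with an estimated correlation). In MHC class II presentation, 0 of 14 measured genes passed (2 higher adjusted over the list alone). The class II list median was 0.32 (camera adjusted p = 0.000148, 0.286 with an estimated correlation). Of cDC2 markers, 2 of 16 measured genes were higher and none was lower (the same adjusted over the list alone). Across the cDC2 list, the median was 0.27 (camera adjusted p = 0.00695, 0.286 with an estimated correlation). Monocyte and macrophage markers moved with these groups. For monocytes, 1 of 12 measured genes was higher and none was lower (the same adjusted over the list alone). Across the monocyte list, the median was 0.57 (camera adjusted p = 0.00433, 0.286 with an estimated correlation). For macrophages, 0 of 12 measured genes passed (1 higher adjusted over the list alone). Across the macrophage list, the median was 1.20, or 0.91 at bounds (camera adjusted p = 0.00205, 0.286 with an estimated correlation). T cell markers moved the other way (median log2 difference -0.60, camera adjusted p = 0.00278, adjusted p = 0.565 with an estimated correlation). After CpG, 8 of 27 lists passed camera (0 with an estimated correlation), the others by median early stress (-0.26) and mitochondrially encoded (-0.18). Mitochondrial transcripts took 0.975% ± 0.0191 of counts in IV-positive and 1.11% ± 0.0477 in IV-negative libraries (SD, n = 3), without overlap. In edgeR's quasi-likelihood test with the Benjamini-Hochberg correction, 45 genes differed (36 higher, 9 lower), and DESeq2 gave 143. The IV label effect in CpG DC2 gave 21 without CpG IV-negative DC2 replicate 2, 22 without CpG IV-positive DC2 replicate 2 and 13 without CpG IV-positive DC2 replicate 3. Hk3, Ube2c and Arpin passed without any 1 library, and both the monocyte and macrophage calls were lost without CpG IV-positive DC2 replicate 1.

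**Figure D4:**
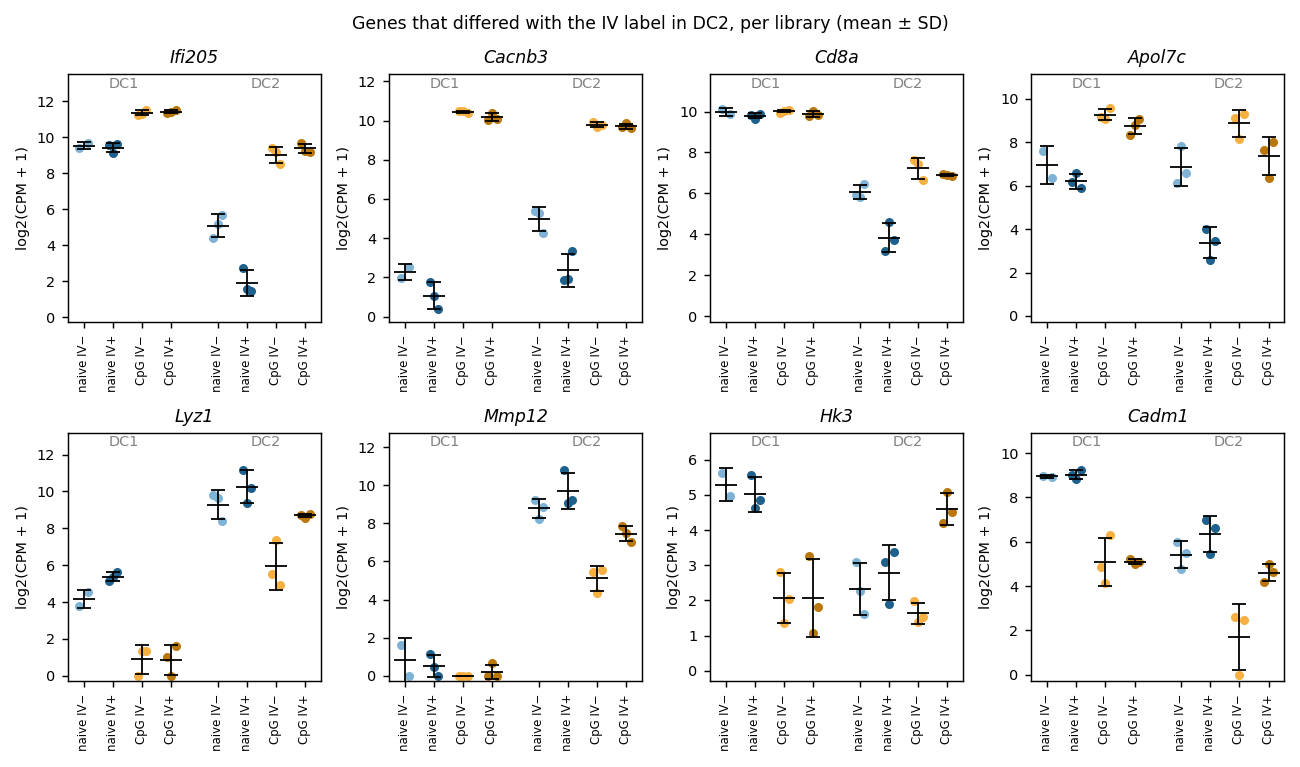
Levels of 8 genes named for the IV comparisons in DC2, as log2(CPM + 1), in the 8 groups; points are libraries, and the line and bars are the mean ± SD. Ifi205, Cacnb3 and Cd8a were lower in IV-positive naive DC2, and Hk3, Mmp12 and Lyz1 were higher in IV-positive DC2 after CpG.

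Tests of whether the IV difference changed after CpG found few genes. In DC1, Iigp1 alone passed: it averaged 64.4 ± 2.38 CPM in naive IV-negative (n = 2) and 3.71 ± 2.91 in naive IV-positive DC1 (n = 3), and 324 ± 38.0 and 277 ± 3.53 after CpG (n = 3 each; difference of log2 differences 3.82 ± 0.48 SE). In DC2, Ifi205 averaged 535 ± 156 and 673 ± 129.8 CPM in IV-negative and IV-positive cells after CpG, against 34.9 ± 14.7 and 3.07 ± 2.19 in naive DC2 (3.87 ± 0.45). Cacnb3 did likewise, at 882 ± 72.5 and 841 ± 79.1 after CpG (2.67 ± 0.42), and Iigp1 in DC2 differed by 2.99 ± 0.56. Aspm, a spindle gene, averaged 22.2 ± 4.40 and 9.44 ± 3.58 CPM in IV-negative and IV-positive naive DC2 and 3.09 ± 1.35 and 9.93 ± 1.94 after CpG (2.89 ± 0.51), with Cenpf, a kinetochore gene, at 2.02 ± 0.37. In the cell cycle list in DC2, 1 of 24 measured genes was higher and none was lower (13 higher adjusted over the list alone). The cell cycle list median was 1.04 (camera adjusted p = 2.31e-12, 0.171 with an estimated correlation). Macrophage markers moved with it: 0 of 12 measured genes passed (5 higher adjusted over the list alone). The macrophage list median was 2.52 (camera adjusted p = 4.51e-05, 0.171 with an estimated correlation). For DC2, 12 of 27 lists passed camera (0 with an estimated correlation), the others by median interferon (0.48), maturation (0.29), class II (0.26), early stress (-0.26), mitochondrially encoded (-0.36), cDC1 (0.64), migratory DC (0.07), B cell (-1.24), NK cell (2.13) and monocyte (1.36); camera's direction for interferon turned without naive IV-positive DC2 replicate 2, and for migratory DC with limma on log2(CPM + 0.1). For DC1, 9 of 27 lists passed camera (0 with an estimated correlation), by median interferon (0.43), chemokine (0.93), NF-kB (0.13), class I (0.21), early stress (-0.26), glycolysis (-0.22), B cell (-0.74), T cell (-0.50) and NK cell (1.64); NF-kB, B cell and NK cell did not pass with the replicate number as a block, and interferon turned without naive IV-negative DC1 replicate 3. Cd38 and Xab2, chosen after their values were seen, completed the 7 genes that passed edgeR's quasi-likelihood test with the Benjamini-Hochberg correction in DC2, against 1 in DC1. The IV label by CpG test in DC2 gave 4 without naive IV-negative DC2 replicate 2, 3 without naive IV-negative DC2 replicate 3, 4 without naive IV-positive DC2 replicate 2, 16 without CpG IV-negative DC2 replicate 3 and 2 without CpG IV-positive DC2 replicate 2, 0 with array weights and 48 with DESeq2. In DC1 it gave 2 without naive IV-positive DC1 replicate 1, 2 without naive IV-positive DC1 replicate 3 and 2 without CpG IV-positive DC1 replicate 3, 0 with limma on log2(CPM + 0.1) and 16 with DESeq2. Iigp1 in DC1 and Ifi205 and Cacnb3 in DC2 passed without any 1 library, while Iigp1, Aspm and Cenpf in DC2 did not. At an unadjusted p of 0.05, 700 genes in DC1 and 1197 in DC2 passed.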

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

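The tests of admixed T or B cells in DC2 after CpG, of admixed DC1, of naive-like DC2 and of monocytes or macrophages were chosen only after the result was seen. Results are listed here because the same effect differed between 2 groups in the test of the difference itself. After CpG, 3531 genes changed differently in DC2 and DC1. Toward DC2 stood Alpl (7.54 on the log2 scale), Gpr31b (7.29), Havcr1 (6.87), Dync2li1 (6.68) and Cd300e (6.22). Toward DC1 stood Ackr1 (-10.55), Kcne3 (-10.04), Flrt3 (-8.79), Cd209d (-8.44) and Gstt1 (-7.99). These fitted differences depend on the prior count where a group had few counts. List medians of that difference were -0.87 for TLR9 and NF-kB signalling, -1.68 for DC maturation, 1.67 for cDC1 markers and -3.11 for migratory DC markers. The IV difference after CpG departed from that in naive nodes for 1 gene in DC1, Iigp1 (3.82). In DC2 it did so for 7 genes, among them Ifi205 (3.87), Iigp1 (2.99), Aspm (2.89), Cacnb3 (2.67) and Cenpf (2.02). Groups of 2 or 3 libraries were not tested for single outlying libraries.

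Cell division genes were higher in IV-positive DC1 (list median 0.81) and DC2 after CpG (0.99, camera adjusted p = 0.286 with an estimated correlation), but not in naive DC2 (-0.18). With all libraries thinned to the lowest total, the medians were 0.89 (adjusted p = 0.00560 with an estimated correlation, 0.00852 before; with the replicate number as a block 0.0409, 0.0785 before) and 0.99 (adjusted p = 9.60e-14 with the preset one). This tests depth weakly, as thinning keeps expected ratios. With the T cell marker level as a covariate, the median in DC1 was 0.90 (adjusted p = 2.48e-37 with the preset one). That of T cell markers went from 0.88 to 0.05, as they are the covariate. Cell cycle genes did not fall, yet T cells stay open, as 49 genes passed against 110. In DC2 after CpG the T cell median was -0.60 and that of B cells 0.06, and the B cell marker level as a covariate left 1.0 (adjusted p = 1.04e-14). A larger share of dividing cells among DC1 and CpG DC2 that the blood reaches is a candidate explanation from the design. It was not tested further, nor were admixed cells of other types.

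In naive DC2, 22 genes were lower in IV-positive cells. After thinning, 100% kept at least as much log2 difference as they lost, a weak test of depth. Admixed DC1 in the IV-negative sort would bring cDC1 markers, and 17 of the 18 gave a median DC1 share of 0.990% and a highest share of 10.8%. For 18 genes, grouped by this result, the highest gave 0% to 48.0% of the excess. Each argues against DC1 alone, but a set so chosen is no test. For Arpin, Cd8a, Ifi205 and, named after its values were seen, Enpp4, the median share accounted for at most 22.3% and the highest for at least 86.5%. For them DC1 and a difference among DC2 cannot be told apart (marker shares from -12.8% to 10.8%). A difference between DC2 that blood reaches and others, admixed migratory DCs (list median -0.67) and the RNA composition that parted these libraries stay open. None was tested further.

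After CpG, 36 genes were higher in IV-positive DC2, and 26 of them were also higher in naive DC2. After thinning, 100% of the 36 kept at least as much log2 difference as they lost, again a weak test of depth. Naive-like DC2 left among the IV-positive cells would bring transcripts that CpG removes. Of these, 40 gave a median share of 0.999% (quartiles 0.275% to 2.18%) and a highest of 10.9%. Of the 26, 21, grouped by passing double that, need at least 29.0%. The other 5, named after their values were seen, need less (Cd209a 3.58%, Cd68 8.31%, Lyz2 14.2%, Sla 16.4%, Mmp12 21.3%). As the 40 hold none of the 36, naive-like DC2 stays open for needs under 100%. Monocytes or macrophages also stay open, with list medians of 0.57 and 1.20 and a lower adjusted p of 0.286 with an estimated correlation, as do the mitochondrial share that parted the same libraries and a difference among DC2 themselves, neither tested further.

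Libraries were also split otherwise into groups of the same sizes. Only the real one of 25 splits gave as many genes for the CpG effect in DC1 (8270 genes against a highest other of 0) and DC2 (7836 against 3662), their difference (3531 against 1773) and the naive cell types (4424 against 2787). The same held for the IV effect in DC1 (110 against 2) and DC2 (68 against 12) and its change after CpG in DC2 (7 against 4). This excluded chance for each alone, uncorrected, but for IV in DC2 only if unpaired, as 3 others drawn part all 6 pairs. For the change of the IV effect in DC1, 3 of 25 splits gave as many (1 against 10), so chance was not excluded. The IV effects within naive DC2 (24 against 2), CpG DC1 (19 against 8) and CpG DC2 (45 against 1) allow only 10 splits, too few for a share under 0.05. The IV effect in naive DC1, with a group of 2, was not split. Of all 32 DC1 splits that part all 5 pairs, added after the results were seen, only the real one gave as many genes for the IV effect (110 against 8). Of the 24 others drawn, 19 part fewer and call up to 2. In CpG DC1, 3 other splits part all 3 pairs, as the real one does, and call 0 genes. The 6 that part fewer call up to 8.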

How the results depend on the processing

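Chosen after seeing the data were the tests with limma on log2(CPM + 1), robust edgeR and library totals only. Across the settings that kept all libraries, the counts for both CpG effects, for the CpG effect DC2 minus DC1 and for naive DC2 minus DC1 stayed within 1.5 times the main count. The IV counts that moved further follow by setting. With array weights they were 233 for DC1, 111 for naive DC1 and 0 for the IV label by CpG test in DC2. With DESeq2 they were 334 for DC1, 156 for DC2, 90 for naive DC1, 83 for naive DC2, 100 for CpG DC1, 143 for CpG DC2, 16 for the IV label by CpG test in DC1 and 48 for the IV label by CpG test in DC2. With limma on log2(CPM + 0.1) they were 22 for DC2, 34 for naive DC1, 46 for CpG DC1 and 0 for the IV label by CpG test in DC1. With the replicate number as a block they were 103 for DC2, 42 for naive DC1, 47 for naive DC2, 38 for CpG DC1, 77 for CpG DC2, 2 for the IV label by CpG test in DC1 and 23 for the IV label by CpG test in DC2. With a fit to only the groups compared they were 38 for DC2, 83 for naive DC1, 5 for naive DC2, 20 for CpG DC2 and 6 for the IV label by CpG test in DC1. With limma on log2(CPM + 5) they were 36 for naive DC1, 41 for naive DC2, 69 for CpG DC1, 91 for CpG DC2 and 3 for the IV label by CpG test in DC1. With quantile normalization they were 71 for naive DC1, 49 for naive DC2 and 2 for the IV label by CpG test in DC1. With limma on log2(CPM + 1) they were 44 for CpG DC1 and 2 for the IV label by CpG test in DC1. With library totals only they were 12 for CpG DC1 and 2 for the IV label by CpG test in DC1. With robust edgeR they were 2 for the IV label by CpG test in DC1. Of 324 list tests, 127 passed with the preset and 29 with the estimated correlation. A fit to only the groups compared holds all libraries for the CpG effect DC2 minus DC1, so it gave no separate value there. The cause of these moves was not tested.

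Leaving out 1 library in turn gave 7503 to 8100 genes for the CpG effect in DC1, 7421 to 7750 in DC2, 2949 to 3689 for their difference, 3416 to 4204 for naive DC2 minus DC1, 13 to 123 for the IV label in DC1, 16 to 77 in DC2, 4 to 19 in naive DC1, 8 to 34 in naive DC2, 0 to 24 in CpG DC1, 13 to 66 in CpG DC2, 1 to 2 for the IV label by CpG test in DC1 and 2 to 16 in DC2. The libraries that moved an IV count by over 1.5 times were, for DC1, 13 without naive IV-negative DC1 replicate 2, 61 without naive IV-negative DC1 replicate 3, 73 without naive IV-positive DC1 replicate 1, 51 without naive IV-positive DC1 replicate 3, 66 without CpG IV-negative DC1 replicate 1, 33 without CpG IV-negative DC1 replicate 3 and 64 without CpG IV-positive DC1 replicate 3. For DC2 they were 43 without naive IV-negative DC2 replicate 1, 16 without naive IV-negative DC2 replicate 2, 41 without naive IV-positive DC2 replicate 1, 45 without CpG IV-positive DC2 replicate 1, 35 without CpG IV-positive DC2 replicate 2 and 31 without CpG IV-positive DC2 replicate 3. For naive DC1 they were 4 without naive IV-negative DC1 replicate 2, 11 without naive IV-negative DC1 replicate 3, 10 without naive IV-positive DC1 replicate 2 and 4 without naive IV-positive DC1 replicate 3, where a group left with 1 library is assumed to vary like the others. For naive DC2 it was 8 without naive IV-negative DC2 replicate 2. For CpG DC1 they were 4 without CpG IV-negative DC1 replicate 1, 1 without CpG IV-negative DC1 replicate 3, 0 without CpG IV-positive DC1 replicate 1, 10 without CpG IV-positive DC1 replicate 2 and 5 without CpG IV-positive DC1 replicate 3. For CpG DC2 they were 21 without CpG IV-negative DC2 replicate 2, 22 without CpG IV-positive DC2 replicate 2 and 13 without CpG IV-positive DC2 replicate 3. For the IV label by CpG test they were 2 without naive IV-positive DC1 replicate 1, 2 without naive IV-positive DC1 replicate 3 and 2 without CpG IV-positive DC1 replicate 3, and 4 without naive IV-negative DC2 replicate 2, 3 without naive IV-negative DC2 replicate 3, 4 without naive IV-positive DC2 replicate 2, 16 without CpG IV-negative DC2 replicate 3 and 2 without CpG IV-positive DC2 replicate 2. The cause was not tested.

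Among genes named for passing, 7217 of 7652 values kept their direction and side of the threshold with all libraries (426 lost the call, 9 reversed), and 6910 of 7595 with 1 library left out (685 lost, 0 reversed). Lists kept 1418 of 1518 values with all libraries and 1159 of 1291 without 1. Reversed in DC1 after CpG under quantile normalization were Uqcrfs1 (-0.00285), mt-Rnr1 (-0.36), mt-Rnr2 (-0.18) and mt-Co1 (-0.36, and -0.14 with library totals only), and in DC2 Atp5b (-0.0201) and mt-Co1 (-0.56, and -0.26 with library totals only). Slco5a1 reversed in the CpG effect DC2 minus DC1 with limma on log2(CPM + 5) (0.0432). With 1 library left out, camera's direction for interferon-stimulated genes turned without naive IV-positive DC2 replicate 2 in the IV label effect in DC2 (medians -0.44 to 0.0198 over the libraries left out) and in naive DC2 (-0.97 to 0.0238). It also turned without that library in the IV label by CpG test in DC2 (0.11 to 1.01), and without naive IV-negative DC1 replicate 3 in that test in DC1 (-0.35 to 0.75). For cDC1 markers in CpG DC1 it turned without CpG IV-negative DC1 replicate 3 (-0.67 to 0.0469). For migratory DC markers in the IV label by CpG test in DC2 it turned with limma on log2(CPM + 0.1) (0.11). The cause was not tested.

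In simulated data, 2-fold changes were found for 49% of genes in the CpG effect in DC1, 50% in the IV effect in DC1, 28% in CpG DC2 and 3% in the IV label by CpG test in DC1, and 4-fold changes for 72%, 80%, 57% and 40%. False calls there made up 13.1% of all calls in the IV label by CpG test in DC2, 7.37% in naive DC1 and 2.06% (naive DC2) to 6.85% (naive DC2 minus DC1) in the others, against a threshold of 5%.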

Other observations

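Values given for single libraries were chosen after they were seen, and the lists were fixed before. Genes that act on vessels changed in both directions after CpG. In DC1, 10 of 24 measured genes rose and 5 fell (the same adjusted over the list alone), with Adm, a vasodilator peptide (6.95 ± 0.77), Arg2 (7.47 ± 0.60) and Lta (5.78 ± 0.56) among the rises. Across the vessel factor list, the median was 1.06 (camera adjusted p = 0.335, 0.496 with an estimated correlation). In DC2, 9 of 24 measured genes rose and 7 fell (9 and 8 adjusted over the list alone); Vegfa fell (-3.90 ± 0.30), and Nos2, which makes nitric oxide, had no counts in naive DC2 and rose at least 46.8-fold. The vessel factor list median was 0.03 (camera adjusted p = 0.644, 0.814 with an estimated correlation). Kdr, the main receptor of vascular endothelial growth factor, rose in DC1 from 1.17 ± 0.653 to 163 ± 33.2 CPM (SD, n = 5 and 6; 6.99 ± 0.47 SE) and in DC2 from 9.62 ± 7.03 to 503 ± 87.6 (n = 6 and 6; 5.81 ± 0.32), while Pecam1 fell (-1.13 ± 0.37 and -2.41 ± 0.28). Endothelial markers as a list did not pass camera in DC1 or DC2. Among adhesion and trafficking receptors in DC1, 9 of 27 measured genes rose and 14 fell (the same adjusted over the list alone), with Cxcr3 and Ccr2 falling (-6.10 ± 0.59 and -5.58 ± 0.43). The receptor list median was -1.14 (camera adjusted p = 0.568, 0.825 with an estimated correlation). In DC2, Cx3cr1 fell (-6.58 ± 0.48) and Cxcr5, a receptor that guides cells to B cell follicles, rose (4.44 ± 0.31).

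Metabolic lists did not pass after CpG. Cholesterol synthesis genes as a list were lower in IV-positive DC1, although 0 of 18 measured genes passed (the same adjusted over the list alone). The cholesterol synthesis list median was -0.55 (camera adjusted p = 3.15e-07, 0.0303 with an estimated correlation and 0.0788 when the replicate number was also a block). In DC1 after CpG, mt-Co1 changed by 0.43 ± 0.08 with the sign reversed under quantile normalization (-0.36).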
